A study of Mus musculus with 6 samples.

How the data were processed

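RNA of mouse C2C12 cells on day 3 of differentiation was measured in 6 libraries, 3 from control cells with a scrambled hairpin and 3 from cells with a stable hairpin against Adamtsl2. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) messenger RNA was selected, and paired reads of 150 bp were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts in Subread 1.5.2, DESeq2 and the build GRCm38 were used; the aligner, the annotation release, the strand setting and the DESeq2 version are not given in the sources used here.

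The deposited table held 16854 genes with 1 normalised signal per library, which the authors made from gene counts divided by a size factor per library. It also held the log2 fold change, the p-value and the adjusted p-value of the authors' own comparison, per the file headers. Within each library, 100% of values were whole multiples of the value of 1 read, within a tolerance of 0.01 reads, so whole reads were recovered. Recovered reads totalled 37346439 to 50329438 per library. At this depth 1 read was worth 0.829 to 1.26 normalised units, and a count of 0 allowed up to 3 reads per library. Of the genes, 16806 were found by identifier in GENCODE M21 (GRCm38), which gave chromosome, position, exonic length and GC content, and 48 were not. Genes with a blank symbol (23) or a repeated symbol (24) were named by identifier.

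Because the values were normalised, limma 3.58.1 (R 4.3.3) was the test, as laid down beforehand for normalised values. It was fitted to log2(value + 1) with a mean-variance trend, the authors' scaling, no block and no covariates, two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low genes. Genes with a value of at least 10 in at least 3 libraries were tested (16245), and 609 were not. Where a group had 1 to 3 reads in all, the ratio of summed reads, scaled by the size factors, is given with an exact 95% binomial counting interval, and where it had 0 reads the fold is a bound against 3 reads per library. Differences of single genes rest on 3 against 3 libraries, for which an exact two-sided permutation test cannot go below 0.1.

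Before the data were examined, 15 primary and 21 secondary gene lists were fixed. Each was tested with camera (preset correlation 0.01), adjusted over the 36 lists, with camera at an estimated correlation and fry beside it, and members were counted over all genes and adjusted over the list alone. Genes named were fixed by rule: Adamtsl2; up to 8 with the largest change in each direction among genes past the threshold, with groups fully separated, a mean of at least 100 and a symbol other than Gm numbers, Rik clones or mitochondrial genes; up to 2 members per direction of each primary list and 1 of each secondary list by smallest adjusted p, or the most abundant where none passed; and 11 anchor genes (Myod1, Myog, Myf5, Mymk, Mymx, Myh3, Ckm, Axin2, Lef1, Ctnnb1 and Wnt9a). Not every gene given by the rule is reported here. Other genes named were chosen after their values were seen. Lists share members, for example Bmp4 and Lgr6.

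Alternatives fixed beforehand were no filter and a minimum of 50, pseudocounts of 0.5 and 5, TMM and upper-quartile scaling, limma without trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, each library left out, an adjusted p of 0.01, and a 2-fold minimum. edgeR called 7344 genes and DESeq2 called 8461. Counts of list members without the third knockdown library, its combination with an estimated correlation, and edgeR without it were added after seeing the data. Replicates were checked for duplicates by a chi-square test of recovered reads: per gene it was 3.88 for knockdown libraries 1 and 2 and 6.86 to 15.9 for pairs of controls, where 1 is sampling noise, so no pair was counted as 1 sample.

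The procedure was tested on simulated reads drawn from the means of the control libraries, the depths of these libraries and the spread estimated from them. With 6 libraries it recovered 4% of 100 genes changed 2-fold and 47% of 100 changed 4-fold, with 1 false call among 16245 genes. With the third knockdown library left out it recovered 83% and 95%, with 4 false calls. For 6 libraries, the spread was estimated with the third knockdown library included and was given to every simulated library. Far fewer genes were changed than in the data. These rates therefore do not describe recovery or false calls in the data themselves. A list lowered 2-fold was called with either correlation and 0 of the other lists were, and a chromosome 4 shift of 0.5 over 837 genes was found as 0.453. The simulated genes varied independently of each other, so the simulation could not test false list calls that arise from correlated genes. Near-identical genes, such as the clustered myosin heavy chains Myh1, Myh4 and Myh8, the Ifit3 and Hspa1b pairs and ribosomal protein genes with pseudogenes, can share reads, as can overlapping and antisense genes where strand was not used, so their values are uncertain to that extent.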

Results

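C2C12 is a mouse myoblast line whose confluent cells leave the cell cycle and fuse into multinucleated myotubes when serum is reduced. RNA was taken on day 3 of differentiation in 2% horse serum from 2 groups of 3 libraries: control cells carrying a scrambled short hairpin RNA, and cells with a stably expressed hairpin against Adamtsl2. Adamtsl2 encodes a secreted glycoprotein of the extracellular matrix that binds fibrillin microfibrils. The title of the series places the question in Wnt signalling during myogenesis. The comparison asks which genes differed between these 2 groups of cells. Effects of the depletion cannot be told apart here from off-target effects of the hairpin or from other differences between the stably modified cells. Messenger RNA was selected by its poly(A) tail and sequenced as paired 150 bp reads. Counts recovered from the deposited values totalled 43632911, 37346439 and 50329438 in control libraries 1 to 3 and 49367857, 48612567 and 39913603 in knockdown libraries 1 to 3.

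Adamtsl2 (ENSMUSG00000036040, GRCm38 chromosome 2, 27079379 to 27108981, plus strand, a protein-coding gene) fell from a normalised count of 1299 ± 30.5 (SD, n = 3) in control to 17.6 ± 8.49 (SD, n = 3) in the knockdown. Its control values were 1325, 1266 and 1307, and its knockdown values were 23.2, 21.8 and 7.83. The log2 fold change was -6.26 ± 0.41 (SE), with an adjusted p of 1.1e-04 (limma, Benjamini-Hochberg). The muscle genes Myog, on chromosome 1, and Mymk, near Adamtsl2 on chromosome 2 (27061636 to 27072179), fell by a similar amount (-6.36 ± 0.12 and -6.51 ± 0.12). The fall of Adamtsl2 therefore does not by itself measure the direct action of the hairpin. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow.

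Knockdown cells held less RNA of 59 of 60 sarcomere genes and 48 of 56 genes of S phase and mitosis than control cells, and more RNA of 24 of 30 interferon response genes. Of 16245 genes tested, 3519 were higher and 3823 lower in the knockdown at an adjusted p under 0.05, together 45.2% of genes. At least 2-fold changes were found for 2541 of the higher and 2687 of the lower genes, and at least 16-fold changes for 380 and 608. The 3 knockdown values lay wholly on one side of the 3 control values for 62.6% of genes, where chance gives 10%. Without the third knockdown library, which differed most from the others, 6269 genes were higher and 6485 lower, and all 7342 genes called with 6 libraries kept their call and direction. The edgeR quasi-likelihood test on the recovered reads called 3765 genes higher and 3579 lower.

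**Figure D1:**
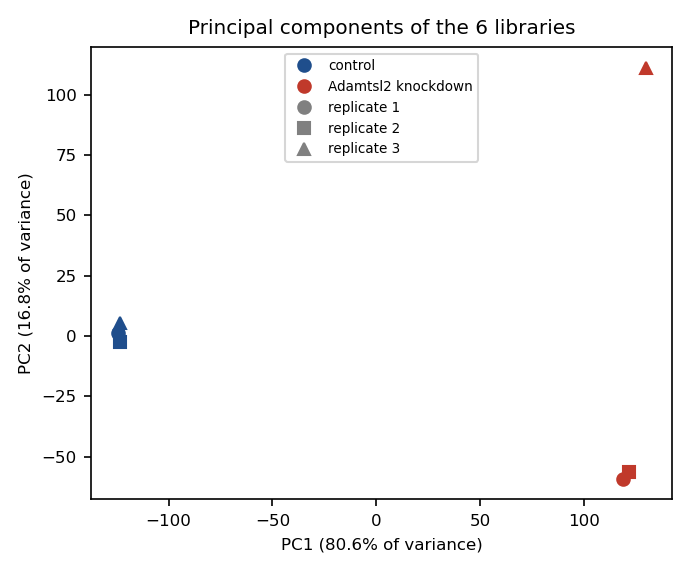
Scores of the 6 libraries on the first 2 principal components of log2 normalised counts over 16245 genes, with colour for the group and marker shape for the replicate number. The first component (80.6% of variance) parts the groups, and on the second (16.8%) knockdown library 3 lies at 111 while libraries 1 and 2 lie at -59.1 and -56.4.

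The third knockdown library differed from the first and second by more than control libraries differed from each other. Across genes, Pearson correlations of log2 values were 0.993 to 0.995 among controls, 0.996 between knockdown libraries 1 and 2, and 0.917 and 0.920 between those libraries and the third. Malat1, a nuclear noncoding RNA picked after the values were seen, took 2.83% of reads in that library, against 0.302 to 0.515% in the others. Protein-coding genes took 93.6% of its reads, against 97.7 to 98.0% elsewhere, and processed pseudogenes 0.734%, against 0.313 to 0.454%. Counts without this library are given beside each gene group.

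Among genes with a mean of at least 100, the largest rises included Clec3b, which encodes the plasminogen-binding protein tetranectin, at a log2 change of 11.33 ± 0.26 (SE, n = 3 per group, as for all log2 changes here), and Igfbp3, an insulin-like growth factor binding protein, at 10.69 ± 0.23. Tnxb, a tenascin of connective tissue, rose by 9.88 ± 0.56, and Col4a5, a basement membrane collagen chain, by 9.31 ± 0.51. Man1a, a Golgi mannosidase, had 3 control reads, all in library 2, and rose 1767-fold (95% counting interval 604 to 8569). Chodl, a transmembrane lectin, had 2 control reads, both in library 2, and rose 1481-fold (410 to 12231). Six3, a homeobox gene, had 0 control reads and was at least 341-fold higher, or 176-fold without the third knockdown library, with 3 reads per library taken as the floor; these intervals and floors cover counting error alone. The largest falls were those of Galnt6, an O-glycosylation enzyme with 1 read, in library 1, among the knockdown libraries (11675-fold lower, counting interval 2095 to 461189), Cdh11, a mesenchymal cadherin (-11.21 ± 0.92), and the skeletal myosin heavy chain Myh4 (-11.14 ± 0.51). Myh8, Actn2, Mef2c, Dhrs7c and Cap2 completed this group, with log2 changes of -10.33, -10.74, -10.65, -11.07 and -10.52. With 1 knockdown library left out, Cdh11 ranged from -12.32 to -10.52, Mef2c from -11.57 to -9.91 and Cap2 from -11.93 to -9.59, each lowest without library 3 and highest without library 2, 2 and 1. Actn2 anchors actin at the Z-disc and Mef2c is a muscle transcription factor.

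**Figure D2:**
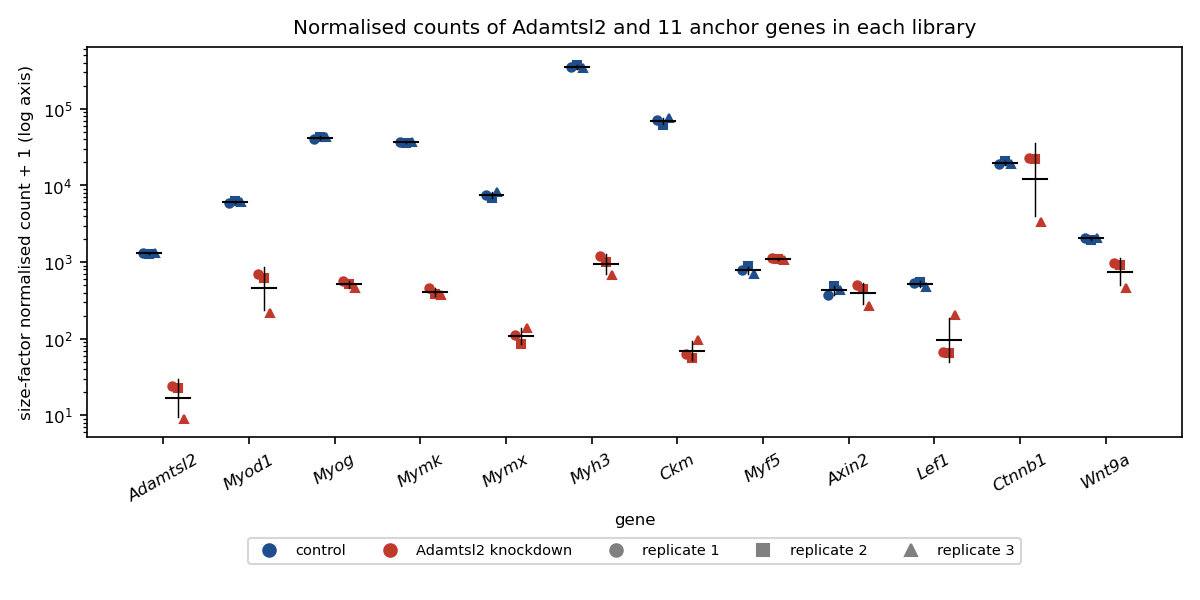
Size-factor normalised counts plus 1 (log axis) of Adamtsl2 and the 11 anchor genes in each library, with bars at the mean and SD of the log2 values of 3 libraries per group. Myog lies near 42192 in control and 514 in the knockdown, while Ctnnb1 in knockdown library 3 (3360) lies far below libraries 1 and 2.

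Of 60 sarcomere genes tested, 59 were lower in the knockdown, with a median log2 change of -7.53 (median unchanged to 2 decimals with 1 member at its count bound), and 60 were lower when p was adjusted over the list alone. Embryonic myosin Myh3 fell from 355521 ± 19946 to 958 ± 272 (SD, n = 3), a log2 change of -8.57 ± 0.24, and fast myosin Myh1 fell by 9.06 ± 0.17. The list was lower than other genes in camera (adjusted p = 1.3e-31) and at adjusted p = 0.031 with an estimated correlation. Without the third knockdown library 60 members were lower. The list then passed in camera with the preset correlation (adjusted p = 1.8e-24) but not with an estimated one (adjusted p = 0.31). Excitation-contraction coupling genes moved the same way: 28 were tested, 23 were lower and 3 higher, with the same counts adjusted over the list alone, and camera gave adjusted p = 1.0e-08 (adjusted p = 0.031 with an estimated correlation). The calsequestrin Casq2, which stores calcium in the sarcoplasmic reticulum, fell by 8.27 ± 0.11 and its partner Hrc fell by 8.12 ± 0.11, whereas Fxyd1, a regulator of the sodium pump, rose by 5.97 ± 0.48 and the phosphatase Mtm1 by 1.91 ± 0.19. With the third library removed, the list had 4 members higher and 24 lower. Its camera adjusted p was then 1.0e-07 with the preset correlation and 0.31 with an estimated one.

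Genes of muscle energy metabolism were lower in 27 of 30 cases and higher in 1, or 27 and 2 adjusted over the list alone. Muscle creatine kinase Ckm fell from 69473 ± 6852 to 70.5 ± 21.6 (log2 -9.96 ± 0.23) and the glycogen phosphorylase Pygm fell by 7.61 ± 0.18. The member that passed upwards was the phosphorylase kinase subunit Phkg1 (1.78 ± 0.45, adjusted p = 0.021), with knockdown values of 153, 169 and 481; its adjusted p was 0.071 to 0.072 with any 1 control library left out. In camera the adjusted p was 6.2e-10, with adjusted p = 0.12 with an estimated correlation. When the third library was left out, 2 were higher and 27 lower. At the neuromuscular junction, 12 of 16 genes were lower (12 lower and 1 higher adjusted over the list alone, 3 higher and 12 lower without the third library). Chrng and Chrna1, subunits of the acetylcholine receptor, fell, with log2 changes of -6.80 ± 0.14 and -5.27 ± 0.13. The list had a camera adjusted p of 3.7e-05 and adjusted p = 0.42 with an estimated correlation.

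Of 27 myogenic transcription factors, 16 were lower and 7 higher (17 and 7 adjusted over the list alone). Myog, which drives terminal differentiation, fell from 42192 ± 1449 to 514 ± 51.7 (log2 -6.36 ± 0.12), and Myod1, which commits cells to the muscle lineage, from 6070.2 ± 209 to 509 ± 259 (-3.75 ± 0.45). Smyd1, a muscle methyltransferase, fell by 8.48 ± 0.26. Myf5, an early determination factor, was higher by 0.47 ± 0.13 (adjusted p = 0.025, and 0.080 to 0.10 when control library 1 or 3 or knockdown library 1 or 2 was left out; 0.069 with a replicate block). Id3, an inhibitor of basic helix-loop-helix factors, rose by 3.14 ± 0.12. The camera adjusted p was 0.030, and adjusted p = 0.21 with an estimated correlation. Without the third library, 17 were lower and 8 higher.

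The genes of myoblast fusion and adhesion were split. Mymk and Mymx, the membrane proteins that fuse myoblasts, fell, with log2 changes of -6.51 ± 0.12 and -6.10 ± 0.20, and Itgb1bp2, a muscle integrin-binding protein, fell by 7.89 ± 0.19. Vcam1, an adhesion receptor, rose by 2.58 ± 0.16 and Elmo1, a regulator of Rac, rose by 3.74 ± 0.26. In all, 17 of 37 were lower, 4 higher and 16 not past the threshold (17 lower and 5 higher adjusted over the list alone). The camera adjusted p of 0.028 became adjusted p = 0.65 with an estimated correlation. Leaving out the third library gave 16 higher, 19 lower and a camera adjusted p of 0.29.

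**Figure D3:**
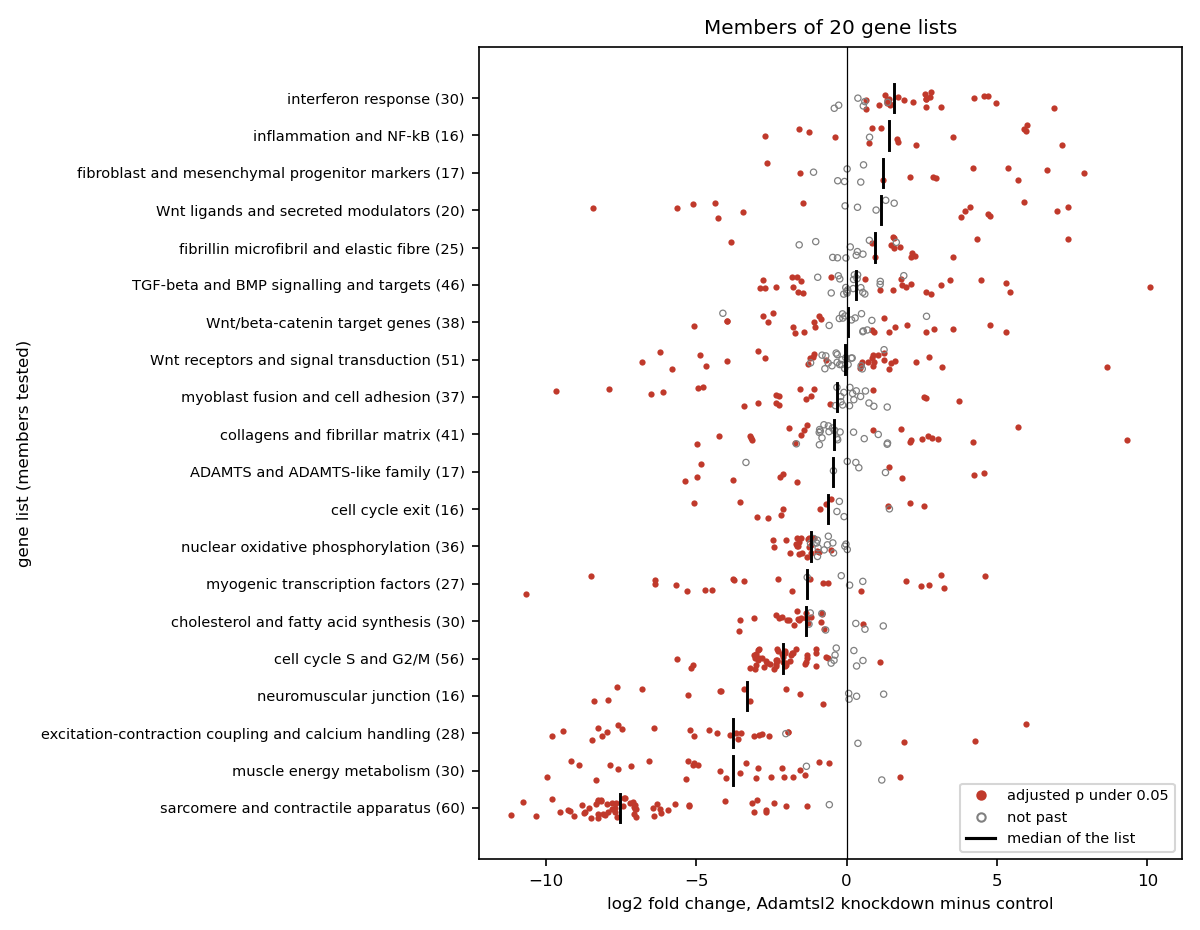
Log2 fold changes (Adamtsl2 knockdown minus control) of the members of 20 gene lists, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at the median of each list and lists ordered by that median. Sarcomere genes lie lowest (median -7.53) and interferon response genes highest (median 1.59).

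Wnt genes changed in both directions. Among ligands and secreted modulators, the antagonists Sfrp2 and Sfrp4 rose by 6.998 ± 0.22 and 7.37 ± 0.38, while the ligands Wnt10a and Wnt6 fell, with log2 changes of -5.62 ± 0.25 and -4.38 ± 0.26. Wnt9a fell from 2034 ± 70.2 to 781 ± 275 (SD, n = 3; log2 -1.45 ± 0.29, adjusted p = 0.0088). Of the 20 tested, 8 were higher and 7 lower (9 and 7 adjusted over the list alone), with a camera adjusted p of 0.31. With the third library removed, 10 were higher and 7 lower.

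Among Wnt receptors and transducers, Lrp6, a co-receptor, was higher by 1.24 ± 0.11, and the receptor Fzd9 fell by 6.81 ± 0.34. Prickle1, of the planar polarity pathway, fell by 4.68 ± 0.26, and its relative Prickle2, with 3 control reads, rose 760-fold (counting interval 260 to 3686). Of 51 tested, 18 were higher and 13 lower (19 and 14 adjusted over the list alone), and camera gave adjusted p = 0.95; the median (-0.06) and mean were negative while the test direction was up. Ctnnb1, which encodes beta-catenin, did not pass (log2 -0.72 ± 0.76, adjusted p = 0.48). Its value of 3360 in knockdown library 3 compared with 22966 and 22287 in libraries 1 and 2, and without the third library its log2 change was 0.20 (adjusted p = 0.0085). Without that library the list had 29 members higher and 17 lower.

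Beta-catenin target genes were higher in 11 and lower in 13 of 38 cases (12 and 14 adjusted over the list alone), with a camera adjusted p of 0.95. Axin2, a widely used readout of the pathway, was at 430.2 ± 59.2 in control and 403 ± 118 in the knockdown (log2 -0.13 ± 0.27, adjusted p = 0.71), and at 0.13 log2 without the third library (adjusted p = 0.33). Lef1, a transcription factor of the pathway, fell by 2.43 ± 0.47 (adjusted p = 0.0071), and the receptor Lgr6 fell by 3.96 ± 0.27. Bmp4 rose by 5.30 ± 0.32 and Wisp2 by 3.53 ± 0.14, while Wisp1 fell by 1.405 ± 0.12. The median of this list was 0.06 and its mean -0.04, while the test direction was up. When the third library was left out, 19 members were higher and 15 lower.

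Genes of fibrillin microfibrils and elastic fibres were mainly higher: 13 of 25 rose and 1 fell, with the same counts adjusted over the list alone. Fbln7 rose by 7.36 ± 0.31 and Efemp1 by 4.35 ± 0.20, both of the fibulin family, and the microfibril protein Mfap4 fell by 3.84 ± 0.26. The camera adjusted p was 0.0075, against adjusted p = 0.53 with an estimated correlation. Without the third library, 18 were higher and 3 lower. Of 17 other ADAMTS and ADAMTS-like genes, 4 were higher and 7 lower, the same adjusted over the list alone (8 and 9 without the third library; camera adjusted p = 0.42). Adamtsl1 and Adamtsl4 rose by 4.23 ± 0.27 and 4.57 ± 0.40, whereas the proteases Adamts16 and Adamts14 fell, with log2 changes of -5.37 ± 0.20 and -4.97 ± 0.25.

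Collagens and fibrillar matrix genes went both ways, with 11 of 41 higher and 10 lower (13 and 12 adjusted over the list alone) and a camera adjusted p of 0.94. Col1a1, the main chain of type I collagen, fell from 317446 ± 22972 to 10709.8 ± 3738 (log2 -4.96 ± 0.31) and Col8a2 fell by 4.23 ± 0.21, while Ogn, a small leucine-rich proteoglycan, rose by 2.52 ± 0.16. The median of this list was -0.41 and its mean 0.13, while the test direction was down. With the third library removed, 18 were higher and 19 lower. In the TGF-beta and BMP list, 15 of 46 genes were higher and 11 lower, also adjusted over the list alone, with a camera adjusted p of 0.23. Gdf11, a ligand of the TGF-beta family, fell by 1.44 ± 0.12. When the third library was left out, 28 were higher, 12 lower, and the camera adjusted p was 0.029 (adjusted p = 0.31 with an estimated correlation).

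Genes of S phase and mitosis were lower in 48 of 56 cases and higher in 1 (49 lower and 1 higher adjusted over the list alone). The repressor E2f8 fell by 5.10 ± 0.13 and the activator E2f2 fell by 5.18 ± 0.16, while Mcm4, a subunit of the replicative helicase, was higher by 1.12 ± 0.18. The list median was -2.11, with a camera adjusted p of 2.7e-14 and adjusted p = 0.021 with an estimated correlation. Without the third library, 52 were lower and 2 higher. The camera adjusted p was then 7.3e-12 with the preset correlation and 0.30 with an estimated one. Of 16 genes of cell cycle exit, 9 were lower and 3 higher, the same adjusted over the list alone. Cdkn1c, a cyclin-dependent kinase inhibitor, fell by 5.05 ± 0.26 and Gadd45b, a stress-response gene, fell by 2.61 ± 0.14, while Gas6, a ligand of receptor kinases, rose by 2.56 ± 0.35. The camera adjusted p of this list was 0.039, with adjusted p = 0.45 with an estimated correlation, 0.0511 with a replicate block and 0.16 without the third library, where 10 were lower and 5 higher.

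Among interferon response genes, 24 of 30 were higher and 6 did not pass (26 higher adjusted over the list alone). Ifit3, an antiviral effector, rose from 15.7 ± 1.23 to 437 ± 46.4 (log2 4.71 ± 0.19). The list median was 1.59 (1.59 also with 1 member at its count bound), and camera gave adjusted p = 2.9e-08 and adjusted p = 0.031 with an estimated correlation. With the third library removed, 26 were higher and 1 lower. The camera adjusted p was then 5.1e-06 with the preset correlation and 0.31 with an estimated one. Inflammatory genes were higher in 11 and lower in 4 of 16 cases, also adjusted over the list alone and without the third library, with the chemokine Cxcl12 (3.54 ± 0.17) and the cyclooxygenase Ptgs2 (-1.57 ± 0.12) having the smallest adjusted p in each direction. In camera their adjusted p was 0.017, and adjusted p = 0.21 with an estimated correlation.

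Genes of cholesterol and fatty acid synthesis were lower in 22 of 30 cases and higher in 1 (23 and 1 adjusted over the list alone), among them Mvd, a mevalonate pathway enzyme (-3.07 ± 0.12), with Lpin1, a phosphatidate phosphatase, higher by 0.56 ± 0.14 (adjusted p = 0.019, and 0.0501 to 0.074 when control library 2 or 3 or knockdown library 2 was left out; 0.052 with a replicate block). The camera adjusted p was 1.1e-05, and adjusted p = 0.38 with an estimated correlation. When the third library was left out, 26 were lower and 4 higher. Nuclear genes of oxidative phosphorylation were lower in 22 of 36 cases (23 adjusted over the list alone, 36 without the third library), among them the succinate dehydrogenase subunit Sdhd (-1.69 ± 0.11). Their camera adjusted p was 6.9e-07, and adjusted p = 0.42 with an estimated correlation. Of 12 mitochondrially encoded transcripts, 3 were lower, 2 adjusted over the list alone and 11 without the third library, including mt-Nd2 (-1.22 ± 0.18), with a camera adjusted p of 0.064 and 0.025 without that library, where the adjusted p was 0.58 with an estimated correlation. Among 40 ribosomal protein genes, Rplp0 (-0.81 ± 0.24, adjusted p = 0.037) was the member that passed over all genes, and it did not pass adjusted over the list alone. Its adjusted p was 0.10 to 0.13 when any 1 library other than the third knockdown library was left out, 0.075 with a replicate block and 0.091 with upper-quartile scaling. Of these genes, 31 were lower and 3 higher without the third library (camera adjusted p = 0.81 with all libraries and 5.9e-05 without it, where the adjusted p was 0.64 with an estimated correlation).

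Of 17 fibroblast and progenitor markers, 9 rose and 2 fell, also adjusted over the list alone (11 and 4 without the third library). Ly6a, the progenitor surface antigen Sca-1, rose from 77.0 ± 6.69 to 19025 ± 4912 (log2 7.90 ± 0.20), and Pi16 fell by 2.64 ± 0.13. This list had a camera adjusted p of 0.018, and adjusted p = 0.21 with an estimated correlation. Adipocyte markers were higher in 5 and lower in 1 of 8 cases (6 and 1 adjusted over the list alone, and without the third library), with Plin4, a lipid droplet protein, up by 3.42 ± 0.26 and the fatty acid transporter Cd36 at -8.51 ± 0.98 (-9.66 without knockdown library 3 and -7.70 without library 1). Their camera adjusted p was 0.035, and adjusted p = 0.26 with an estimated correlation. Osteoblast and chondrocyte markers were higher in 10 and lower in 4 of 17 cases (11 and 4 adjusted over the list alone, 12 and 4 without the third library). Phex, a bone endopeptidase, rose by 5.47 ± 0.17 and the bone matrix gene Dmp1 fell by 6.0 ± 1.03 (-7.11 without knockdown library 3 and -4.99 without library 1), with a camera adjusted p of 0.035, adjusted p = 0.45 with an estimated correlation and 0.16 without the third library.

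The other marker lists did not pass as groups. Smooth muscle and pericyte markers were higher in 2 and lower in 7 of 12 cases (camera adjusted p = 0.12), with the intermediate filament gene Des falling from 150507 ± 3307 to 4027 ± 466. Endothelial markers were higher in 2 and lower in 3 of 5 (0.75), leukocyte markers in 3 and 1 of 7 (0.29), and neural and glial markers in 2 and 3 of 9 (0.69). Each of these counts was the same adjusted over the list alone. Cd14, a myeloid co-receptor, rose by 2.96 ± 0.14, Flt1, an endothelial receptor, by 5.27 ± 0.72 (4.50 without control library 2), and Map2, a neuronal microtubule protein, by 7.69 ± 0.40, while the progenitor filament gene Nes fell by 3.27 ± 0.16. For neural and endothelial markers without the third library, 2 and 2 were higher and 5 and 3 lower, and for smooth muscle and leukocyte markers 3 and 3 higher and 7 and 3 lower. The mean of the neural list (0.24) had the opposite sign to its median (-1.14) and test.

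Of 20 reserve and satellite cell genes, 4 were higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.17). The progenitor antigen Cd34 rose from 274 ± 28.3 to 22713 ± 4208 (log2 6.36 ± 0.18), and Heyl, a Notch target, fell by 6.07 ± 0.23. Insulin-like growth factor and imprinted genes were higher in 5 and lower in 11 of 21 cases, also adjusted over the list alone (camera adjusted p = 0.062, and 0.048 and 0.0495 without knockdown library 2 and control library 3; adjusted p = 0.27 with an estimated correlation and all libraries). Igfbp5, a binding protein abundant in differentiating myoblasts, fell from 140197 ± 15613 to 391.6 ± 43.7 (log2 -8.48 ± 0.15). Without the third library, the counts were 8 and 11 for the first of these lists and 8 and 13 for the second.

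The remaining lists did not pass in camera. YAP and TEAD targets were higher in 4 and lower in 6 of 23 cases (adjusted p = 0.85), with the coagulation factor receptor F3 up by 3.73 ± 0.18. Unfolded protein and heat shock genes were higher in 6 and lower in 14 of 29 (0.064), including the serine synthesis enzyme Phgdh at -3.02 ± 0.11. The p53 and apoptosis list had 7 higher and 12 lower of 25 (0.42), with Perp, a desmosomal p53 target, up by 7.78 ± 0.28 and Pmaip1, which promotes apoptosis, at -4.35 ± 0.31. Hypoxia and glycolysis genes were higher in 5 and lower in 12 of 29 (0.10), Ndrg1 rising by 3.56 ± 0.18 and the glycolytic enzyme Tpi1 at -2.33 ± 0.13. Autophagy and atrophy genes were higher in 8 and lower in 3 of 20 (0.19), with the lysosomal protein Lamp2 at 1.36 ± 0.12 and the muscle ubiquitin ligase Trim63 at -3.07 ± 0.16. Immediate early genes were higher in 8 and lower in 8 of 24 (0.81). Adjusted over the list alone, the higher and lower counts of these lists, in the same order, were 4 and 6, 7 and 14, 8 and 12, 5 and 14, 9 and 3, and 9 and 9. With the third library removed, they were 13 and 7, 8 and 18, 11 and 13, 8 and 18, 13 and 6, and 12 and 10. The YAP list's mean (0.14) and test were positive while its median was -0.09, and the mean of the immediate early list (-0.01) was negative while its test was up.

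With the preset correlation 16 of 36 lists passed, and 4 did with an estimated correlation: sarcomere, excitation-contraction coupling, S phase and mitosis, and interferon response. Without the third knockdown library 16 lists, not all the same ones, passed in camera with the preset correlation. With an estimated correlation 0 lists passed without that library, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.302. The 9 other splits of the 6 libraries into 3 and 3 passed 10 to 13 lists with the preset correlation. With an estimated correlation those splits passed 0 lists in camera, 0 also at an unadjusted p under 0.05, where the real split had 8. Those splits mixed control and knockdown libraries in both groups, in unequal numbers. This moved much of the group difference into the spread within groups and left part of it between them. Neither their 10 to 13 lists nor their 0 lists are therefore a measure of chance. Protein-coding genes of chromosome 4 had a median log2 change 0.57 above that of all such genes on autosomes and X. Those of chromosome 5 had one of -0.36 relative to it. Upper-quartile scaling moved the median log2 change of all genes from -0.001 to 0.115, a shift larger in size than the medians of the Wnt receptor, Wnt target, YAP and immediate early lists. The authors' deposited table held 8515 genes past an adjusted p of 0.05, 4370 higher and 4145 lower, of which 3492 and 3787 were called in the same direction here. In the authors' deposited table Adamtsl2 had a log2 fold change of -6.17. Because nothing in the labels says that libraries of a group came from separate cultures, p-values measure only the spread between these samples, which may be technical.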

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

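The counts of list members without knockdown replicate 3, the estimated correlation without that library and edgeR without it were chosen after seeing the data; the other alternatives were planned. Adamtsl2 stayed lower and past the threshold under every alternative run, from -6.52 to -5.79 log2, with a highest adjusted p of 0.0017 (limma, edgeR or DESeq2). Of the other genes given by the naming rule, 108 passed the threshold, and of their 2049 alternative values 2022 kept direction and side, 27 lost the threshold and 0 changed direction. Most of these genes were picked for a large change or a small adjusted p in the same libraries. Their stability was largely assured by that choice. The number of changed genes stayed within 1.5 times of 7342 under each filter, pseudocount, scaling and tool, from 6443 to 8461. An adjusted p under 0.01 left 4828 genes, 2283 higher and 2545 lower, as a stricter threshold must. Upper-quartile scaling moved the median of all genes to 0.115 and edgeR to 0.107; the share of calls that were higher was 53.5% with upper-quartile scaling, against 47.9%.

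With 1 library left out, changed genes ranged from 5101 to 12754, higher genes from 2443 to 6269 and lower genes from 2648 to 6485, with the top value each time without knockdown replicate 3. Axin2 ranged from -0.31 to 0.13 and Ctnnb1 from -1.19 to 0.20. The adjusted p of camera ranged from 0.269 to 0.991 for Wnt receptors, 0.527 to 0.991 for Wnt targets, 0.20 to 0.982 for YAP targets, 5.9e-05 to 0.955 for ribosomal proteins, 0.0129 to 0.290 for myoblast fusion, 0.0289 to 0.365 for TGF-beta and BMP, 0.671 to 0.991 for collagens and 0.0352 to 0.164 for cell cycle exit. Without knockdown replicate 3, members higher were 16 for fusion, 3 for neuromuscular junction, 2 for energy metabolism, 29 for Wnt receptors, 19 for Wnt targets, 28 for TGF-beta and BMP, 8 for ADAMTS, 18 for collagens, 2 for S phase and mitosis, 5 for cell cycle exit and 4 for cholesterol. Members lower were 3 for fibrillin, 19 for collagens, 1 for interferon, 36 for oxidative phosphorylation and 4 for fibroblast markers. Over all 16245 genes, 12754 were called without that library and 7342 with all libraries. Larger member counts are therefore not by themselves particular to these lists. edgeR without that library called 12948 genes, 6489 higher and 6459 lower, and gave Axin2 0.15 and Ctnnb1 0.22, both above 0. The cause of these changes was not tested.

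With an estimated correlation 1 list was higher and 3 were lower in camera. Calls ended at an adjusted p of 0.208 for myogenic factors, 0.654 for fusion, 0.420 for neuromuscular junction, 0.119 for energy metabolism, 0.532 for fibrillin, 0.450 for cell cycle exit, 0.208 for inflammation, 0.381 for cholesterol, 0.420 for oxidative phosphorylation, 0.208 for fibroblast markers, 0.256 for adipocyte markers and 0.450 for osteoblast markers. The estimated correlation was below the preset 0.01 for myogenic factors (-0.013), inflammation (-0.023), fibroblast markers (-0.038) and adipocyte markers (-0.126). It was above 0.01 for the other lists that lost their call. A higher correlation therefore does not account for the loss in the lists where it was lower. Estimated without knockdown replicate 3 as well, 0 lists were higher and 0 lower in camera, 3 were under an unadjusted p of 0.05, and the lowest adjusted p was 0.302. Without that replicate and with the preset correlation, 16 lists passed. The test fry, which asks whether genes of a list move 1 way and does not compare them with other genes, gave 10 lists higher and 21 lower. Its adjusted p was 0.00084 for Wnt ligands, 0.0410 for TGF-beta and BMP and 0.0126 for ADAMTS, and, with the direction opposite to camera, 0.0839 for Wnt receptors, 0.0449 for Wnt targets and 0.826 for collagens. The cause was not tested.

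With the replicate block 6311 genes were changed, 3010 higher and 3301 lower, of which 6229 were called in the same direction without it. Deviations of same-numbered libraries correlated at 0.017, 0.105 and 0.143, and knockdown 1 correlated better with control 2 (0.116) than with its own number. The third library dominated the deviations in the knockdown group, so these values can neither show nor exclude pairing by number. The main test had no block because no label says that equal numbers share a culture. The adjusted p with the block was 0.0516 for Lpin1, 0.0686 for Myf5 and 0.0751 for Rplp0, which passed without it. In camera with the block, cell cycle exit had an adjusted p of 0.0511 and Wnt receptors one of 0.972 with the direction down. Depth limits the genes with 1 to 3 reads in a group, whose ratios have counting intervals spanning more than 10-fold.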

Other observations

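The tests in this part were chosen after the results were seen, and so were the genes named. Among homeobox and T-box genes, families known for specifying position in the embryo and picked here because members had changed, counts are given with no test of the family. Of 11 Hoxa cluster genes tested, 8 were higher and 1 lower in the knockdown, and of 9 Hoxc genes 6 were higher and 2 lower. Hoxa9 rose from 625 ± 49.6 to 2973 ± 591 (SD, n = 3), a log2 change of 2.23 ± 0.17 (SE), while Hoxc13 fell from 1349 ± 105 to 291 ± 49.5 (-2.22 ± 0.16). Of 7 T-box genes, 5 were lower, among them Tbx15, which fell from 8382 ± 60.0 to 845 ± 116 (-3.32 ± 0.14), and Tbx3 (-1.87 ± 0.12). Without the third knockdown library, 8 Hoxa and 7 Hoxc genes were higher, and 5 T-box genes were lower.

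With a control mean of at least 200 and every knockdown library under 10, 69 genes were off in the knockdown, and 77 showed the reverse. H19, an imprinted noncoding RNA, fell from 216128 ± 1234 to 14099 ± 3168 (log2 -3.96 ± 0.22). Xist, the RNA that coats the inactive X chromosome, fell from 57066 ± 4804 to 27833 ± 3792 (-1.04 ± 0.18). Vim, the mesenchymal intermediate filament, rose from 104342 ± 2408 to 241327 ± 10492 (1.21 ± 0.21).

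Other splits of the 6 libraries into 3 and 3 gave 10 arrangements, too few for a share under 0.05. The real split had 7342 changed genes, and 1 of the 10 splits, the real one, gave as many; the highest other had 0 in limma, with at most 474 at an unadjusted p under 0.05. For gene lists past the threshold with the preset correlation, the real split had 16, again given by 1 of the 10 splits, and the highest other had 13. Each other split mixed control and knockdown libraries in both groups, which moved the group difference into the spread within groups. The 0 changed genes there followed from this mixing, so these splits cannot weigh chance for the 7342 genes. The mixing was unequal and left part of the group difference between the groups, so they cannot weigh chance for the 16 lists either.

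The medians of protein-coding genes of some chromosomes were shifted relative to all 13181 such genes on autosomes and X. In knockdown libraries 1 to 3, chromosome 4 (837 genes) had median log2 changes of 0.54, 0.53 and 0.54, and chromosome 5 of -0.36, -0.34 and -0.35. Those of chromosome 1 were -0.32, -0.31 and -0.27, of chromosome 16 0.33, 0.32 and 0.20, and of chromosome 19 -0.25, -0.27 and -0.20. No control library departed from the others by more than 0.033 on any chromosome. Over the first and second knockdown libraries, 72.3% of chromosome 4 genes lay above the median of all these genes. Within chromosome 8, the first and second knockdown libraries had a median of 1.22 from 80 to 100 Mb and of -0.59 from 100 to 120 Mb, against 0.04 for the chromosome. Other chromosomes were not examined by position, so the extent of the shifts along them is not known. The tables argue against the third library as the source (chromosome 4 median 0.55 without it), against gene length and GC content (0.58 after their trends were removed), and against clusters of up to 20 neighbouring regulated genes (permutation p = 1e-04 over 10000 shuffles of blocks, the smallest they can give, a test added after the next one). Longer runs of regulated genes that lie near each other by chance cannot be told apart from whole-chromosome shifts: circular shifts of gene order gave a permutation p of 0.14, but with shifts of the observed size planted they gave a p under 0.05 in only 23% of 100 simulations. A different copy number of chromosomes in the 2 cell populations is a hypothesis that may account for the shifts: chromosome 4 genes of low, middle and high expression had medians of 0.71, 0.41 and 0.57, but DNA was not analysed here.

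The third knockdown library differed from the mean of the other knockdown libraries with an SD over genes 7.79 times that between those libraries: Anxa11, an annexin, was at 60.4 against 993 and 1051, and Ilk, an adhesion kinase, at 33.5 against 1215 and 1183. Gene length and GC content as the whole cause are argued against by a ratio of 7.05 after their trends were removed. Carry-over of control RNA could not be decided. Of 379 genes at least 16-fold lower in the first and second knockdown libraries, 106 (27.97%) lay below both in the third. The wide spread of that library could place genes there even if a small amount of control RNA was added. An earlier test of carry-over, a chi-square of 32.8 per gene over 126 genes near silent in the first and second knockdown libraries, was replaced because these genes lie near the floor. They took 1512 reads in the third library. Those reads correlated with control values at 0.16 and with exonic length at 0.43 (Spearman, across genes). An excess of reads from short transcripts cannot be told apart from other differences: deviations correlated with exonic length at -0.29 (Spearman, across genes, which are not independent replicates), but the first against the second library gave 0.19. No biological explanation was tested, because the labels put this library in the same group as the others.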
